A study of Homo sapiens with 18 samples.

How the data were processed

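Total RNA from A549 cells was measured on 18 single-colour Affymetrix Human Genome U133 (A) arrays, 3 for each of 6 groups given by the labels: 50 µM MGd or mannitol for 4, 12 or 24 h. Each array has a deposited file of probe set signal and detection call (Present, Marginal or Absent), and per the file headers the values are signals, an intensity on a linear scale with 1 value per probe set. The software that made the signals and calls, its version and its settings are not given in the sources used here. The deposited arrays were not scaled to each other, since their trimmed means (2% removed at each end) ranged from 90.5 to 281. The deposited value table of the whole series holds the same intensity multiplied by 1 factor per array, between 0.824 and 2.54, to within 0.0320% above a signal of 200. Low values in it are raised to a floor of 49 to 50, which took in 6811 to 8109 probe sets per array, and its column medians ranged from 87.5 to 122. It is neither logged nor centred, and its target value is not stated. The deposited experiment files name only the chip type, identically for all arrays, so no scan day or chip lot could be used as a batch. No 2 arrays held identical values, and correlations between arrays ranged from 0.781 to 0.909 over log2 signals.

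From the per-array signals, each array was scaled to a common trimmed mean of 183 and log2(signal + 16) was taken, so that a fold change is on that scale and understates the change of low signals. The 68 control probe sets were left out. Probe sets called Present on all 3 arrays of at least 1 group were tested, 7341 of 22283, which left 14874 out for their detection calls. Metallothionein signals reached 94.9% of the highest signal of an MGd array for MT2A and 80.4% for MT1X, so their rises can be compressed at the bright end.

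A means model with 1 coefficient per group was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, 12 residual and 4.55 prior degrees of freedom), and the median residual SD was 0.342 on the log2 scale. Contrasts were MGd against mannitol at each time point, their mean, the differences between the effects of time points, and mannitol at 24 h against 4 h. All tests were two-sided with Benjamini-Hochberg adjustment over the probe sets tested, and calls were made at an adjusted p of 0.05. Each time point has its own mannitol arrays, so no comparison within a time point shares controls with another.

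Gene names came from the platform annotation table: 19071 probe sets had 1 symbol, 1043 several and 2169 none. Of the first, 19059 were matched by gene ID to the RefSeq table of assembly GCF_000001405.40, which changed 0 symbols. Probe sets with several symbols were not named. For gene lists, the probe set with the highest mean log2 signal stood for each of 4893 genes. The 22 lists held 574 entries, of which 326 were tested: metallothioneins, zinc transporters, NRF2 and antioxidant genes, hypoxia-induced genes, glycolysis, heat shock and cytosolic chaperones, the unfolded protein response, the ATF4 and amino acid response, p53 targets, mitosis, replication, cholesterol synthesis, iron and heme, NF-kB, immediate early genes, interferon response, oxidative phosphorylation, proteasome, apoptosis regulators, epithelial and lung markers, and fibroblast and leukocyte markers as signs of other cell types. They were tested with limma camera (preset correlation 0.01), with an estimated correlation beside it, and with fry. The latter asks whether the genes of a list shifted in 1 direction, and not whether they changed more than other genes. Its mixed form counts changes in either direction. The calls of the metallothionein list held with the estimated correlation.

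The groups, tests, gene lists, alternatives and rule for naming genes were set before the data were examined. Eligible to be named were, per time point, up to 10 largest rises and falls among genes that passed, were Present on all 3 arrays of the higher group and had no overlap between the 3 arrays of each group. Up to 4 members of each list with the largest change, and 20 genes named whatever their values, were eligible as well, of which the report prints those with the larger changes, with the 5 largest rises and falls for the average and for the difference between 24 and 4 h. Of those 20, MTF1, MKI67 and EGR1 did not meet the detection filter, and CA9, HSPA1A and HSPA1B were not analysed here.

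Replicate numbers in the labels were checked for pairing through the correlation of deviations from group means over the tested probe sets. MGd and mannitol arrays of the same number had correlations of 0.275, 0.146 and 0.185 at 4 h and of 0.175, 0.132 and 0.137 at 24 h, so the numbers were taken to pair arrays at these time points. The labels do not say what a number marks. Over all groups, 45 pairs of the same number had a median correlation of 0.168 and 90 pairs of different numbers of -0.0899. The main fit, set before the data were examined, has no block, so its values leave this pairing out. A fit with the number as a block was run beside it for each comparison.

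The test was checked on simulated arrays drawn from the means and residual SDs of the 7341 probe sets, with 200 of them changed in each of 10 runs. At 4 h it recovered 6.72% of 1.5-fold, 41% of 2-fold and 88.6% of 4-fold changes, and 4.94% of calls were false. At 12 h the shares were 8.06%, 42.2% and 90%, and at 24 h 6.42%, 40.4% and 88.8%. For the average over time points they were 48.5%, 87.5% and 100%, and for the difference between 24 and 4 h 0.597%, 10.6% and 69.1%. With the 16 tested heat shock genes shifted 1.3-fold, camera called that list in 10 of 10 runs over 4893 genes and called 0 of 200 unshifted lists. All simulated values were drawn independently, without correlation between genes or between arrays of the same number. The runs therefore do not show how camera behaves where the genes of a list vary together.

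Alternatives were quantile normalization, the deposited value table, pseudocounts of 1 and 64, no detection filter, Present on all 18 arrays, an added 1.5-fold threshold, limma with a trend and robust eBayes, only the groups compared, array weights, the replicate block, other choices in camera, and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.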

Results

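Gene expression was measured in A549 cells, an epithelial cell line derived from a human lung adenocarcinoma, after exposure to 50 µM MGd or to mannitol as the control. The labels do not spell out MGd; it is taken here to be motexafin gadolinium, a gadolinium-containing texaphyrin. RNA was collected at 4, 12 and 24 h, with 3 arrays for each treatment at each time point, 18 Affymetrix Human Genome U133 (A) arrays in all. The labels do not say whether replicates came from separate cultures, so the p-values below measure only the spread between these arrays, which may be technical. Before scaling, the trimmed mean signal of the arrays ranged from 90.5 to 281, and the share of probe sets called Present ranged from 26.9% to 41.2%. With 3 arrays per group, the number of arrays limits the precision of every comparison. Of 22283 probe sets, 7341 met the detection filter and were tested.

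The first question was which transcripts differed between MGd and mannitol after 4 h. The metallothioneins, small cysteine-rich proteins that bind zinc, copper and cadmium, rose together. MT1F signal was 12249 ± 1316 (SD, n = 3) with MGd against 332 ± 42.0 (SD, n = 3) with mannitol, a log2 change of 5.14 ± 0.29 (SE). SLC30A1, the plasma membrane transporter that exports zinc from the cytosol, rose from 486 ± 119 to 3281 ± 162 (SD, n = 3 each), a log2 change of 2.74 ± 0.20 (SE). No probe set passed as lower. For both genes all 3 MGd arrays lay above all 3 mannitol arrays.

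In the limma test, 11 of 7341 probe sets passed a Benjamini-Hochberg adjusted p of 0.05 at 4 h, all of them higher with MGd. Of the 11, 9 belonged to metallothionein genes and another was SLC30A1 (adjusted p = 2e-07). The remaining probe set has no gene name in the annotation used and rose by 5.23 ± 0.33 (SE) on the log2 scale. Among the metallothioneins, the log2 changes were 4.62 ± 0.40 (SE) for MT1H, 4.41 ± 0.29 for MT1HL1, 4.02 ± 0.27 for MT1X, 3.27 ± 0.29 for MT2A, 2.90 ± 0.42 for MT1G and 2.08 ± 0.34 for MT1E. The lowest of these adjusted p values was 9.28e-08, for MT1HL1 and MT1X, and the highest was 0.00839, for MT1E, whose call at 4 h was lost without MGd replicate 2 (0.0896) or 3 (0.0668) or mannitol replicate 1 (0.0676) or 2 (0.0561), without the detection filter (0.113) and with only the groups compared in the fit (0.229). MT2A signal was 2468 ± 449 (SD, n = 3) with mannitol and 24136 ± 5798 with MGd. These probe sets can take up transcripts of near-identical family members, so the value of each metallothionein is uncertain. The 2 probe sets of MT1G differed: 1 rose, while the other, Present on 1 of 18 arrays and not tested, had a log2 change of 0.04 ± 0.72 (SE) in a fit of all probe sets. MT1E also differed between its probe sets, since the other had a log2 change of 1.06 ± 0.21 (SE) and missed the threshold (adjusted p = 0.078).

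**Figure D1:**
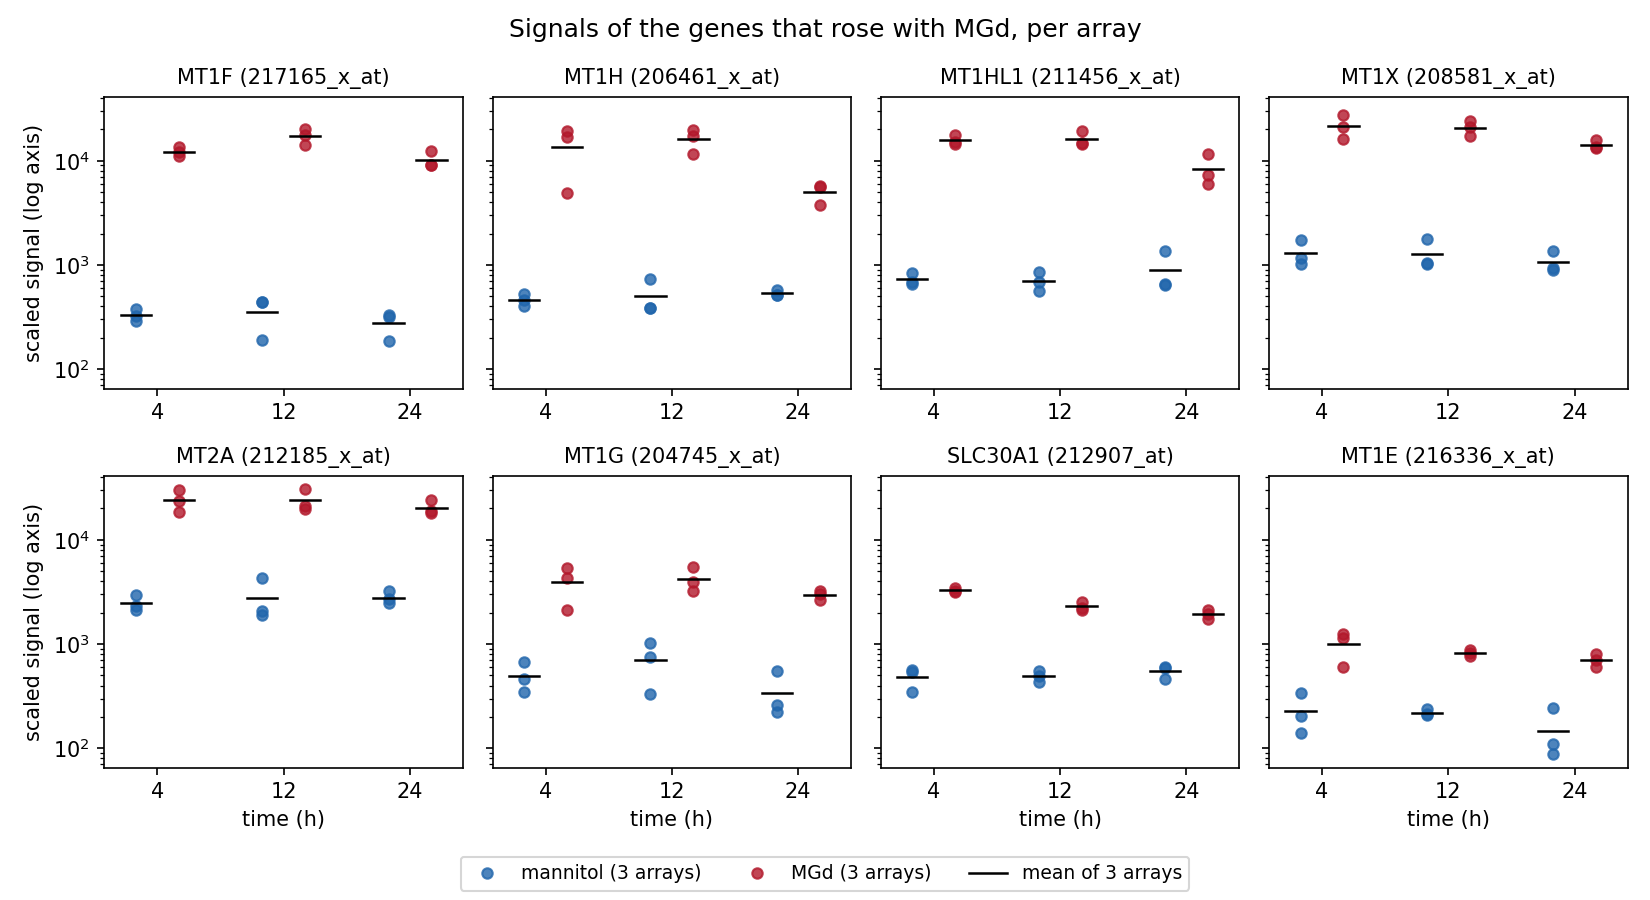
Scaled signal per array (log axis) against time in hours for 1 probe set of each gene among the largest rises, with mannitol arrays in blue, MGd arrays in red and black bars for the mean of 3 arrays. For SLC30A1 the MGd means were 3281, 2306 and 1938 at 4, 12 and 24 h, and the mannitol means lay between 486 and 557.

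Other stress responses were followed through genes and lists chosen before the data were examined. At 4 h the heme oxygenase gene HMOX1 had a log2 change of 0.72 ± 0.33 (SE) and did not pass (limma adjusted p = 0.999). NQO1, TXNRD1 and TXN, oxidoreductase genes of the antioxidant response, had log2 changes of -0.08, -0.03 and 0.03, and GCLM, which encodes the modifier subunit of glutamate-cysteine ligase, 0.56. Of 32 tested NRF2 and antioxidant genes none passed. The angiogenic growth factor gene VEGFA, induced in hypoxia, had a log2 change of 0.41 ± 0.53 (SE). The stress transcription factors DDIT3 and ATF3 had log2 changes of -0.40 and 0.35, the growth and differentiation factor gene GDF15 -0.29 and the transferrin receptor gene TFRC -0.22. CDKN1A, which encodes the cell cycle inhibitor p21, had a log2 change of -1.18 ± 0.32 (SE) and did not pass (limma adjusted p = 0.544). It passed, at -1.65 ± 0.25 (SE, limma adjusted p = 0.00423), when MGd replicate 3 was left out.

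Among 21 gene lists with a tested gene, the metallothionein list alone was shifted at 4 h. All 7 of its tested genes rose, both over all probe sets and adjusted over the list alone, with a median log2 change of 4.02 (limma camera adjusted p = 1.55e-54, and adjusted p = 2.99e-05 with an estimated correlation). Of 8 tested zinc transporters, SLC30A1 rose and 7 did not pass. The list median was -0.06 and its mean 0.27, and SLC30A5 and SLC39A8 had log2 changes of 0.57 and -0.54. Among 16 heat shock and chaperone genes none passed over all probe sets and 1 passed adjusted over the list alone (limma adjusted p = 0.0197). This was CHORDC1, a co-chaperone gene of HSP90, with a log2 change of 0.99 ± 0.25 (SE). HSPH1, DNAJA1 and HSPA4 had log2 changes of 0.88, 0.53 and 0.51, and the list did not pass (camera adjusted p = 0.0964). With fry the adjusted p was 0.361 for this list and 0.189 for the zinc transporters. The mixed form of fry gave 0.0444 and 2.33e-06, which a change of single members can bring about. Of 14 p53 targets none passed over all probe sets and CDKN1A passed adjusted over the list alone (limma adjusted p = 0.0261). PLK2 and BAX had log2 changes of 0.78 and -0.50, and the list had a median of -0.20 (camera adjusted p = 0.304).

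In the other lists no member passed at 4 h, over all probe sets or adjusted over the list alone. Among 22 hypoxia-induced genes the median log2 change was 0.16, with STC2 at 0.60 and ERO1A at -0.53, and among 14 glycolysis genes it was -0.02. Medians were 0.02 for 17 genes of the unfolded protein response, -0.09 for 28 genes of the ATF4 and amino acid response, -0.04 for 28 proteasome genes and 0.03 for 45 oxidative phosphorylation genes. In the last list, NDUFA5 had a log2 change of -0.57 and ATP5PF of 0.42. Cell cycle genes had medians of 0.09 for the 6 tested mitosis genes, PTTG1 at 0.42 among them, and 0.08 for 17 replication genes, with MCM4 at 1.03. Among 14 immediate early genes FOSL1 had a log2 change of -1.29 ± 0.47 (SE) and KLF4 of 0.76, with a list median of 0.12. Medians were 0.17 for 12 apoptosis regulators, with CFLAR at 0.73, and 0.04 for 10 cholesterol synthesis genes, with FDPS at -0.77. The 7 NF-kB genes had a median of 0.15 and the 5 interferon response genes of -0.05, with IRF1 at 0.69. The 16 iron and heme genes had a median of -0.04 and the 6 epithelial and lung markers, keratins among them, also of -0.04. Of markers of other cell types, 0 of 10 fibroblast markers met the detection filter, so that list gave no value, and 2 of 12 leukocyte markers were tested, CD14 at -0.19 and CD53 at -0.15.

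**Figure D2:**
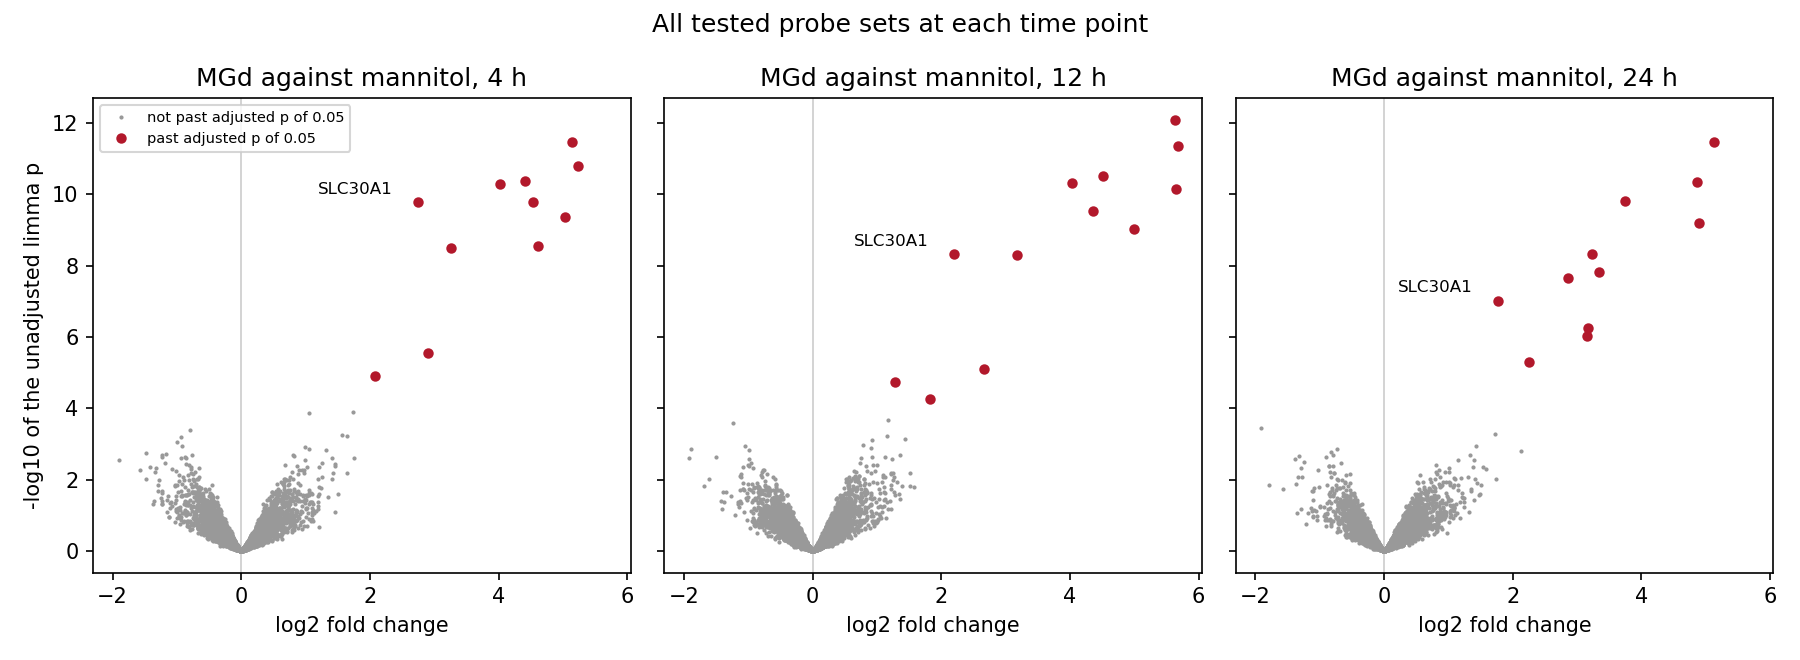
Log2 fold change of MGd over mannitol against -log10 of the unadjusted limma p for 7341 probe sets, 1 panel per time point, with red points past an adjusted p of 0.05. The 11, 12 and 11 red points at 4, 12 and 24 h all lie to the right of 0.

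After 12 h the same transcripts led. MT1F was at 17445 ± 3055 (SD, n = 3) with MGd against 356 ± 144 with mannitol, a log2 change of 5.63 ± 0.29 (SE). MT1H rose by 4.99 ± 0.40 (SE) on the log2 scale, MT1HL1 by 4.51 ± 0.29, MT1X by 4.03 ± 0.27, MT2A by 3.17 ± 0.29 and MT1G by 2.67 ± 0.42. SLC30A1 rose from 492 ± 63.4 to 2306 ± 220 (SD, n = 3 each), a log2 change of 2.20 ± 0.20 (SE). None of the 7341 probe sets passed as lower in this fit.

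In limma, 12 probe sets passed at 12 h, the 11 called at 4 h and the other probe set of MT1E (log2 change 1.27 ± 0.21 SE, adjusted p = 0.0122). That call was lost without MGd replicate 2 (0.112), MGd replicate 3 (0.0853) or mannitol replicate 1 (0.112), without the detection filter (0.221) and with only the groups compared (0.175). The adjusted p was 5.91e-09 for MT1F and 3.98e-06 for SLC30A1. The MT1E probe set called at 4 h rose by 1.83 ± 0.34 (SE) with an adjusted p of 0.0334, and missed the threshold under several alternatives, among them quantile normalization (0.0669), with a pseudocount of 1 (0.0602), without the detection filter (0.24) and when any of the 6 arrays of 12 h was left out. MT1G missed it when MGd replicate 2 was left out (adjusted p = 0.0667), without the detection filter (0.0513) and with only the groups compared (0.0562).

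HMOX1 had a log2 change of 0.02 ± 0.33 (SE) at 12 h, NQO1 of -0.02, TXNRD1 of 0.03, GCLM of -0.10 and TXN of -0.12. VEGFA had a log2 change of 0.27, DDIT3 of -0.36, ATF3 of -0.18, CDKN1A of -0.34, GDF15 of 0.30 and TFRC of -0.19. None of these genes passed, and the lowest adjusted p among them was 0.977. The metallothionein list was again the only list shifted, with 7 of 7 genes higher and a median of 4.03 (limma camera adjusted p = 6.34e-47, and adjusted p = 6.7e-05 with an estimated correlation). SLC30A1 was the 1 zinc transporter of 8 that rose, and the list median was 0.05, with SLC39A7 at 0.38. Among 16 iron and heme genes none passed over all probe sets, and CPOX, the gene of coproporphyrinogen oxidase in heme synthesis, passed adjusted over the list alone (limma adjusted p = 0.0119). Its log2 change was 1.43 ± 0.35 (SE). FECH and PPOX, which encode later enzymes of the same pathway, had log2 changes of 0.51 and 0.52, and the list median was 0.18. The list did not pass in camera (adjusted p = 0.176, and 0.26 with an estimated correlation), while fry gave an adjusted p of 0.0236 (0.0165 in its mixed form). Among 16 heat shock genes FKBP4, a co-chaperone, passed adjusted over the list alone (limma adjusted p = 0.0207) at 0.91 ± 0.23 (SE), with HSPB1 at 0.51 and HSPH1 at -0.45. With each of 21 lists adjusted alone at each time point, some such passes arise by chance, here and at 4 h.

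No gene of the other lists passed at 12 h. Medians were 0.02 for NRF2 and antioxidant genes, 0.00 for hypoxia-induced genes, 0.14 for glycolysis genes and -0.14 for the unfolded protein response. They were 0.02 for the ATF4 and amino acid response, -0.26 for p53 targets, with GADD45A at -0.62, and -0.05 for mitosis genes. Replication genes had a median of 0.12, with FEN1 at 1.36 ± 0.59 (SE) and MCM6 at 0.75. Medians were 0.05 for cholesterol synthesis, -0.44 for the NF-kB genes, with CXCL1 at -0.92 and NFKBIA at 0.66, and -0.04 for immediate early genes. They were 0.04 for interferon response genes, with IRF1 at 0.64, 0.02 for oxidative phosphorylation, with NDUFA1 at -0.76, and 0.04 for the proteasome. Apoptosis regulators had a median of 0.13, with BCL2L1 at 0.49. Epithelial markers had a median of 0.26, with MUC1 at 0.94 ± 0.62 (SE), and leukocyte markers of -0.13. The 3' to 5' signal ratio of GAPDH, a measure of RNA quality, was 1.00 ± 0.08 (SD, n = 3) with MGd and 1.19 ± 0.04 with mannitol at 12 h. The exact two-sided permutation p was 0.1, the smallest that 3 arrays against 3 allow. The same ratio of ACTB was 1.04 ± 0.16 (SD, n = 3) and 1.24 ± 0.19 (exact p = 0.3). No other technical measure reached the smallest p at any time point, so chance may account for the GAPDH ratio.

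After 24 h the metallothioneins and SLC30A1 were still higher with MGd. MT1F was at 10146 ± 1856 (SD, n = 3) against 278 ± 80.1, a log2 change of 5.14 ± 0.29 (SE), and MT2A at 20391 ± 3077 against 2794 ± 376. MT1X rose by 3.74 ± 0.27 (SE) on the log2 scale, MT1HL1 by 3.23 ± 0.29, MT1H by 3.18 ± 0.40, MT1G by 3.16 ± 0.42, MT2A by 2.86 ± 0.29 and MT1E by 2.25 ± 0.34. This MT1E probe set was Present on 2 of 3 MGd arrays, so it fell outside the rule for naming genes. The other MT1E probe set had a log2 change of 0.61 ± 0.21 (SE) and did not pass, and its MGd and mannitol arrays overlapped. SLC30A1 rose from 557 ± 79.1 to 1938 ± 196 (SD, n = 3 each), a log2 change of 1.78 ± 0.20 (SE). No probe set passed as lower.

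In limma, 11 probe sets passed at 24 h, and all 11 had been called at 4 h and at 12 h. The adjusted p was 2.53e-08 for MT1F, 8.87e-05 for SLC30A1 and 0.00329 for MT1E, which missed the threshold with only the groups compared (0.0897). HMOX1 had a log2 change of 0.25 ± 0.33 (SE), NQO1 of 0.23, TXNRD1 of 0.15, GCLM of 0.38 and TXN of 0.00. VEGFA had a log2 change of -0.06, DDIT3 of 0.24, ATF3 of 0.48, CDKN1A of 0.19, GDF15 of 0.38 and TFRC of 0.03, and none of these genes passed.

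The metallothionein list was the only list shifted at 24 h, with 7 of 7 genes higher and a median of 3.18 (limma camera adjusted p = 1.11e-53, and adjusted p = 3.26e-05 with an estimated correlation). In the zinc transporter list SLC30A1 rose and 7 of 8 genes did not pass, with SLC39A8 at 0.80 and SLC39A14 at -0.32 and a list median of -0.10. No other list held a gene that passed, over all probe sets or adjusted over the list alone. Medians were 0.04 for NRF2 and antioxidant genes, -0.06 for hypoxia-induced genes, with ERO1A at -0.87 and SLC2A1 at -0.66, and 0.08 for glycolysis genes. Heat shock genes had a median of 0.06, with CHORDC1 at 0.72 and HSPA2 at -0.69, and the unfolded protein response of -0.07. Medians were 0.07 for the ATF4 and amino acid response, 0.11 for p53 targets, 0.12 for mitosis genes and 0.17 for replication genes, with PRIM1 at 0.66. Cholesterol synthesis genes had a median of 0.12, with HMGCS1 at 0.61 and IDI1 at 0.54, and iron and heme genes of 0.04. The NF-kB genes had a median of 0.11, with CXCL2 at 1.02 ± 0.54 (SE) and CXCL1 at 0.95, and immediate early genes of 0.01, with ZFP36 at -0.64. All 5 interferon response genes had log2 changes below 0 and a median of -0.19, with IRF1 at -0.54 (camera adjusted p = 0.261). Medians were 0.04 for oxidative phosphorylation, with NDUFB7 at 0.62, -0.03 for the proteasome, 0.00 for apoptosis regulators, -0.03 for epithelial markers and -0.15 for leukocyte markers.

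**Figure D3:**
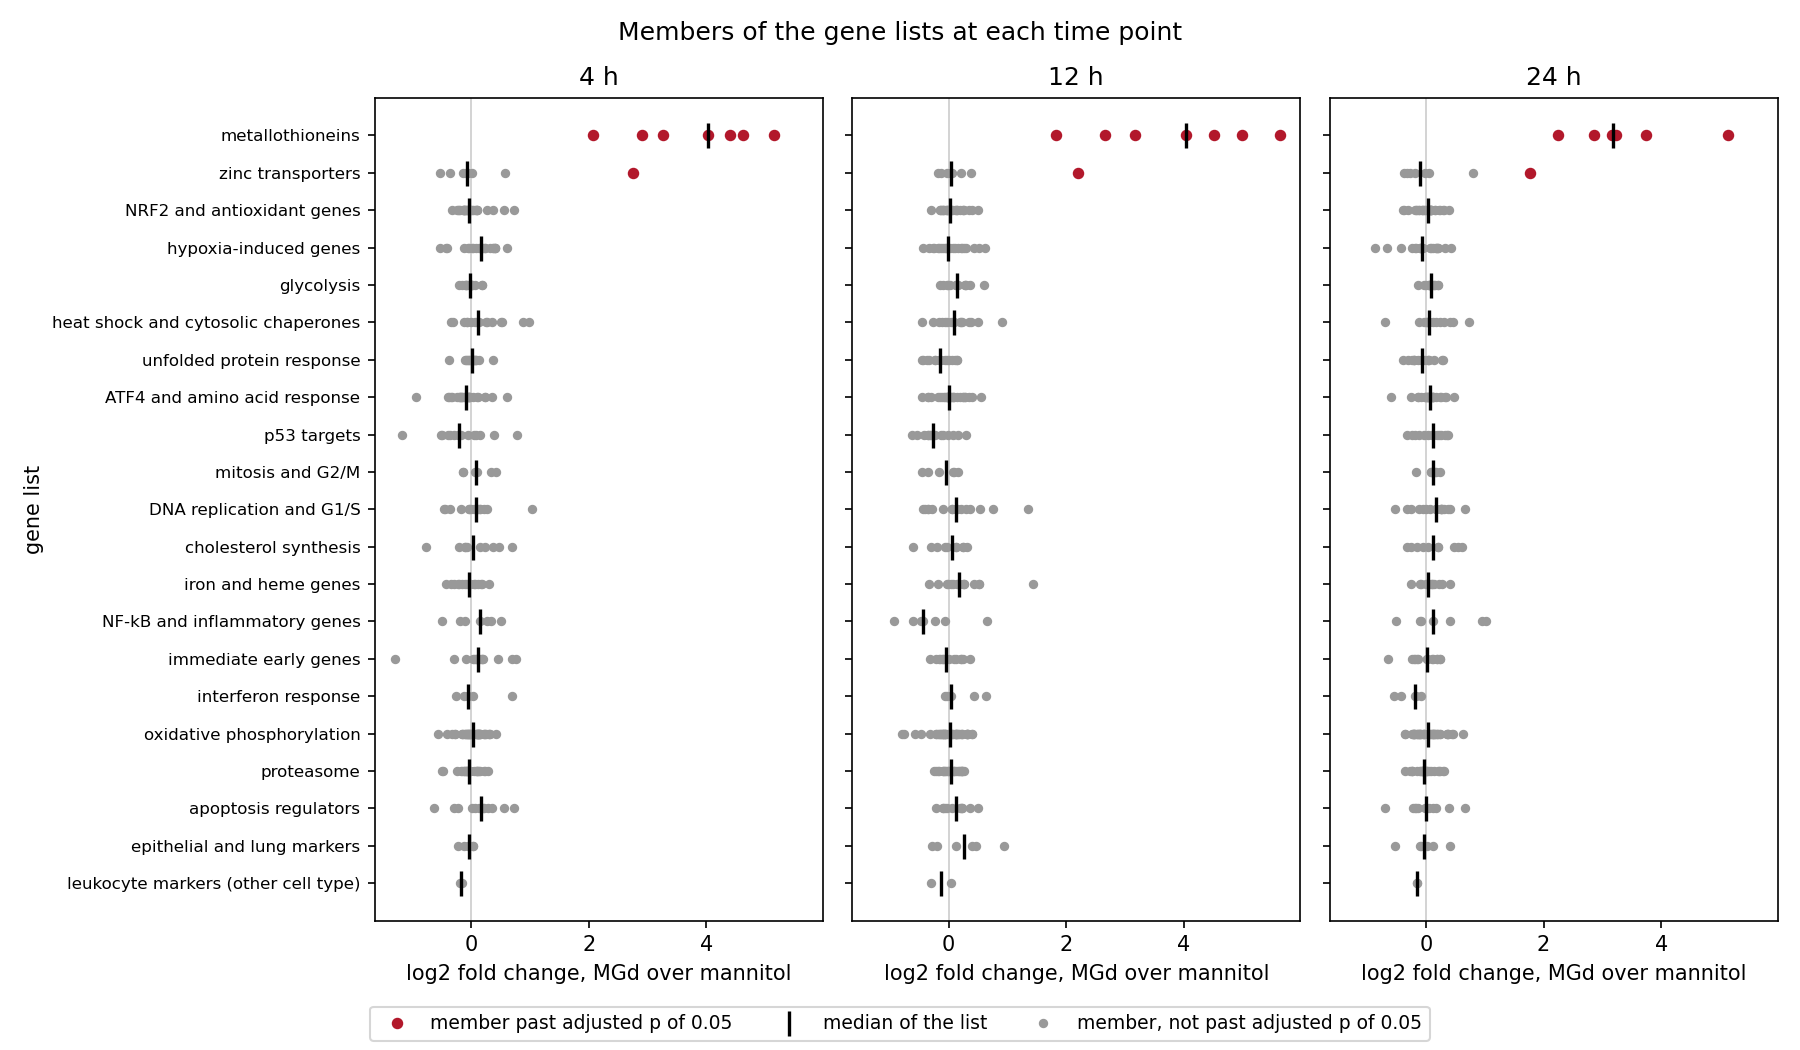
Log2 fold change of MGd over mannitol for each tested member of 21 gene lists at 4, 12 and 24 h, with red points for members past an adjusted p of 0.05 and black marks for list medians. The 7 metallothioneins lie between 1.83 and 5.63, and SLC30A1 is the red point among the zinc transporters.

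The effect shared by the time points was estimated with 9 arrays against 9. On average MT1F rose by 5.30 ± 0.17 (SE) on the log2 scale, MT1H by 4.26 ± 0.23, MT1HL1 by 4.05 ± 0.17, MT1X by 3.93 ± 0.16 and MT2A by 3.10 ± 0.17, and SLC30A1 by 2.24 ± 0.11. ACP2, which encodes a lysosomal acid phosphatase, was the 1 probe set called lower, by 0.76 on the log2 scale (SE 0.13). Its mean signals at 4, 12 and 24 h were 154, 218 and 189 with MGd and 309, 319 and 349 with mannitol, and the 3 MGd arrays lay below the 3 mannitol arrays at each time point. However, ACP2 passed at no single time point (limma adjusted p = 0.272, 0.966 and 0.707). Present calls were made on 2, 2 and 3 of the MGd arrays and on 3, 2 and 2 of the mannitol arrays.

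In limma 13 probe sets passed for this average, 12 higher and 1 lower. The adjusted p was 2.21e-12 for MT1F, 7.74e-10 for SLC30A1 and 0.0104 for ACP2. The call of ACP2 was lost with the replicate number within each time point as a block (log2 change -0.76 ± 0.14 SE, adjusted p = 0.182) and without the detection filter (adjusted p = 0.194), where LTBP4, which encodes a protein that binds latent TGF-beta, was called lower instead (log2 change -1.37 ± 0.23 SE, adjusted p = 0.0441).

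Whether the response changed with time was tested as the difference between the MGd effects of pairs of time points. SLC30A1 had a log2 difference of -0.97 ± 0.28 (SE) between 24 and 4 h, -0.55 ± 0.28 between 12 and 4 h and -0.42 ± 0.28 between 24 and 12 h. MT1H had a difference of -1.44 ± 0.57 (SE) between 24 and 4 h and MT1F of -0.01 ± 0.41. For MT1X it was -0.28 ± 0.38 (SE) in the probe set used above and -1.20 ± 0.46 in its other probe set. No probe set passed in limma for any of the 3 differences, over 7341 probe sets each. The lowest adjusted p was 1 for 24 against 4 h, 0.0777 for 12 against 4 h and 1 for 24 against 12 h. At an unadjusted p under 0.05 there were 281 probe sets for 24 against 4 h and 343 for 12 against 4 h, where chance gives 367, and fewer for 24 against 12 h (3.31%). With the replicate number as a block these counts were higher than 367. They were 388 within each time point and 393 over all time points for 24 against 4 h. They were 524 and 532 for 12 against 4 h, and 389 and 387 for 24 against 12 h. Whether they exceed the chance count by more than its spread was not tested. No gene list was shifted, and the metallothionein list had a median difference of -0.28 between 24 and 4 h (camera adjusted p = 0.214). Adjusted over the zinc transporter list alone, the difference of SLC30A1 between 24 and 4 h passed (limma adjusted p = 0.0254). It no longer did with the replicate number within each time point as a block (limma adjusted p = 0.0512). With the number over all time points as a block it passed (0.0266).

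The mannitol arrays gave the background over time. Between 4 and 24 h with mannitol, SLC30A1 had a log2 difference of 0.21 ± 0.20 (SE), MT2A of 0.18 ± 0.29, MT1F of -0.28 ± 0.29 and MT1G of -0.56 ± 0.42. No probe set passed in limma (lowest adjusted p = 0.796), and 340 had an unadjusted p under 0.05 where chance gives 367. With the replicate number over all time points as a block, 473 did and none passed. In simulated arrays with 200 changed probe sets, the same test recovered 41.5% of 2-fold changes and 88.2% of 4-fold changes for this comparison.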

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

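The tests below that leave out single arrays, simulate changes or split the arrays were chosen before their results were seen; the others were chosen after the result was seen. 4 genes were picked out because their MGd effect differed between time points when adjusted over their own gene list alone. They lie in 3 of 63 combinations of list and comparison, where chance gives 3.15, and none passed over all probe sets.

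SLC30A1 rose less at 24 h than at 4 h, by a log2 difference of -0.97 ± 0.28 (SE), with a limma adjusted p = 0.0254 over the 8 zinc transporters alone. Scaling between arrays was examined with the 200 uncalled probe sets nearest in signal to SLC30A1, picked separately in each treatment. Their median change from 4 to 24 h in MGd arrays minus that in mannitol arrays was -0.0059, more than 2 SE from the value of SLC30A1. All arrays were scaled to 1 trimmed mean, which in part holds such a median near 0, so it cannot decide on this cause. It shows only that probe sets of like signal did not shift together. Under quantile normalization the difference of SLC30A1 was -0.99 ± 0.275 (SE). Drift of the mannitol controls is argued against as the whole cause, since the MGd arrays alone fell by 0.76 on the log2 scale from 4 to 24 h (SE 0.20). Dependence on single arrays stays open: the difference stayed between -1.09 and -0.75 whichever of 12 arrays was left out, but its p exceeded 0.05 without any 1 of 5 arrays, 0.0843 at most, without mannitol 4 h replicate 2. With the replicate number within each time point as a block, the difference was again -0.97 ± 0.28 (SE) but its adjusted p over the list alone was 0.0512, as the residual degrees of freedom went from 12 to 6. With the number over all time points as a block it was -0.97 ± 0.27 (SE, limma adjusted p = 0.0266). A weaker response at 24 h also stays open, as a hypothesis that may reflect chance among the 63 combinations.

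MT1H had a log2 difference of -1.81 ± 0.57 (SE) between 24 and 12 h and MT1HL1 of -1.28 ± 0.41, each with a limma adjusted p = 0.0237 over the 7 metallothioneins alone. IRF1 had a difference of -1.23 ± 0.42 (SE) between 24 and 4 h, with a limma adjusted p = 0.0465 over the 5 interferon response genes alone.

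The 2 MT1G probe sets moved apart: averaged over time points, 1 rose by 2.91 ± 0.26 (SE) on the log2 scale and the other had a change of -0.32 ± 0.42 (SE), with all probe sets in the fit. Signal from other metallothionein transcripts in the rising probe set may account for this and stays open. That the other does not detect its transcript stays open as well, as it was Present on only 1 of 18 arrays. With so few Present calls it cannot show whether its transcript changed, so these values do not decide between the 2 explanations. No biological explanation was tested.

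Few probe sets outside the metallothioneins and SLC30A1 passed. Low power may hide moderate changes at a single time point, as 41% of simulated 2-fold changes were recovered at 4 h. Spread shared by arrays of the same replicate number stays open as a reason. A block for the number called 13 probe sets for the average over time points, as did the fit without it. The count at an unadjusted p under 0.05 went from 278 to 414, where chance gives 367, and the median residual SD from 0.342 to 0.305. A true absence of other changes stays open.

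Other splits of the arrays were counted for each result. For the average over time points, 1 of 100 splits within time points, the real one, gave as many as 13 calls. The highest other gave 2. This is the smallest share that 100 splits can give, and it makes a chance split of these arrays unlikely. The splits ignored replicate numbers. They cannot speak to differences between cultures if the replicates were not separate cultures. At 4 h the real split gave 11 calls and the highest other 1, at 12 h 12 and 0, and at 24 h 11 and 0, with 1 of 10 splits as large in each. Of the gene lists, 1 was called at each time point in the real split. The highest other gave 4, 2 and 3 lists at 4, 12 and 24 h, with 7, 6 and 8 of 10 splits as large. Every other split still leaves the treatments unequal between its sides, so part of the metallothionein shift remains in it. Which lists the other splits called was not recorded, so these list counts cannot show how often chance gives a list. At 4 and 24 h the 3 other splits that part all same-numbered pairs gave at most 1 list, and the higher counts came from the 6 splits that keep a pair together. In these comparisons, 10 splits are too few for a share under 0.05. Where the real count was 0, every split reaches it, 10 of 10 for mannitol at 24 against 4 h and 100 of 100 for each difference between time points, so these counts decide nothing. The highest other was 0 for mannitol, 1 for 24 against 4 h, 3 for 12 against 4 h and 0 for 24 against 12 h.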

How the results depend on the processing

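All alternatives were chosen before the data were examined. A scan or hybridisation batch was not run, because the experiment files give none. With probe sets Present on all 18 arrays, 5 probe sets were called at 4, 12 and 24 h each and 5 for the average, all among those called before, because 3601 probe sets were then tested and 6 or more of the earlier calls were not among them. The same filter shifted 2 gene lists at 4 h and 2 at 12 h, the zinc transporters joining with fewer members. Under the other alternatives, leaving arrays out aside, the counts were 10 to 11 at 4 h, 10 to 13 at 12 h, 10 to 11 at 24 h and 12 to 13 for the average, 0 for each difference between time points and 0 for mannitol over time, and 1 list at each time point. Quantile normalization and the deposited value table moved the median of all probe sets by less than 0.02. With arrays left out, the called numbers were 10 to 12 at 4 h, 9 to 13 at 12 h, 11 to 15 at 24 h and 13 for the average. Differences between time points ranged from 0 to 1 for 24 against 4 h, 0 to 2 for 12 against 4 h and 0 to 1 for 24 against 12 h, mannitol over time from 0 to 1, and lists from 1 to 3 at 4 h, 1 to 3 at 12 h and 1 at 24 h. For these differences and for mannitol over time the added probe sets were DAXX without MGd 4 h replicate 3, TXLNA without MGd 4 h replicate 1 or 3, HPS1 without MGd 24 h replicate 3 and IDS without mannitol 24 h replicate 1. The added lists were heat shock genes, higher, without MGd 4 h replicate 1, and zinc transporters, higher, and p53 targets, lower, without MGd 4 h replicate 3 or MGd 12 h replicate 3. The cause was not tested.

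With the replicate block within each time point, 11, 12 and 11 probe sets were called at 4, 12 and 24 h, 12 for the average and 0 for each difference. With the block over all time points the counts were 11, 13, 11 and 13, and 0 for the differences and for mannitol over time. At 12 h the same-numbered arrays had correlations of 0.173, 0.0823 and 0.208, 1 of them under the 0.1 set for pairing, so the numbers were not taken to pair arrays at 12 h. Each MGd array of 12 h did correlate best with the mannitol array of its own number, with at most 0.00034 for another number. Over all groups, same-numbered pairs ranged from 0.044 to 0.325 and pairs of different numbers from -0.274 to 0.0598. The data thus show a spread shared by number at 12 h too, though the design does not state it, and the main fit leaves it out. The block over all time points took 1 of the 2 MT1E probe sets from the calls at 12 h (adjusted p = 0.0762) and added CYP1B1, higher, and PLOD2, lower (0.0305 each). This PLOD2 probe set had a log2 change of -0.95. Another stood for PLOD2 among the hypoxia-induced genes, none of which lay below -0.44 at 12 h. The block within each time point also ended the calls of ACP2 and, over the zinc transporters alone, of the SLC30A1 difference between 24 and 4 h (adjusted p = 0.0512). The block over all time points kept that SLC30A1 call (adjusted p = 0.0266). At an unadjusted p under 0.05, counts rose with the blocks from 337 to 457 and 466 at 4 h, from 361 to 527 and 546 at 12 h, from 276 to 384 and 362 at 24 h and from 278 to 420 and 414 for the average. For named genes, only the other scalings and pseudocounts, the block within each time point and the left-out arrays were compared. Of 253 such alternative values for named genes past the threshold, 240 kept direction and side and none reversed. Of 2805 for the others, 1 passed, CDKN1A. These counts leave out the detection filters, the fit of only the groups compared and the block over all time points. Some MT1E and MT1G calls were lost under 1 or more of those. Dim signals limit the rest: 14874 probe sets were left out for detection calls. Without the detection filter 4 of them were called, SON (adjusted p = 0.0185), NR2E1 (0.0185) and FUBP1 (0.0224), higher at 12 h, and LTBP4 (0.0441), lower for the average. A separate fit of the left-out probe sets called 0.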

Other observations

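MT1M, another metallothionein gene, was Absent on all arrays and not tested, so its values are near background. At 4 h its scaled signal was 20.1 to 69.6 on the 3 MGd arrays and 3.48 to 4.98 on the 3 mannitol arrays. The groups overlapped at 12 h, 6.48 to 30.1 against 1.64 to 9.15, and at 24 h, 5.02 to 9.92 against 3.55 to 10.5. It was chosen after its values were seen.

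Beyond the called probe sets, the fold changes of the time points showed little relation across probe sets, which are not independent replicates. Over the 7328 probe sets called in no comparison, Pearson's r of the log2 changes was -0.0678 between 4 and 12 h, -0.00596 between 4 and 24 h and 0.0289 between 12 and 24 h, and Spearman's rho was -0.0931, 0.00425 and 0.0425.

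Array brightness before scaling was higher with MGd in the mean at each time point, and over the 9 arrays of each treatment it was 201 against 166. Permuting treatments within time points, with replicate numbers ignored, gave an exact two-sided permutation p = 0.238, in a test chosen after the values were seen. At 4 h the unscaled trimmed mean was 198 ± 79.4 (SD, n = 3) with MGd and 157 ± 47.2 with mannitol (exact two-sided permutation p = 0.5). At 12 h it was 209 ± 61.5 and 155 ± 4.67 (exact p = 0.2) and at 24 h 195 ± 66.0 and 185 ± 91.9 (exact p = 1), where 0.1 is the smallest p that 3 arrays against 3 allow. These tests ignored replicate numbers too. Within same-numbered arrays at 4 h, MGd was the brighter each time, at 281 against 190, 124 against 103 and 188 against 179. At 24 h the values went both ways, at 271 against 274, 165 against 90.5 and 150 against 192.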
